A study of Cuscuta campestris with 13 samples.

How the data were processed

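Small RNAs of *Cuscuta campestris* were measured in 9 libraries and cleaved RNA ends (PARE, or degradome) in 4. Per the labels' protocols, the parasite was grown on *Pelargonium zonale* in 24 h of light per day at 21 °C, seedlings were taken at 3 to 6 cm, and the non-infective vine was the top 3 cm. Segments at the prehaustorial and emerged stages were taken after induction by far-red light and touch. Small RNAs were gel purified and made into NEBNext libraries, and PARE libraries carried fragments of 20 nt, per the labels' protocols. Trim Galore and Bowtie are named, without version or role, per the submitters' processing notes. The genome build, the miRNA reference and the number of mismatches allowed are not given in the sources used here.

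The authors deposited a raw read count per miRNA family and library, per the file headers, and beside each count its RPM, the reads scaled to an equal library total. The table lists 38 rows, with miR7782 present as 2 separate rows, and its counts are whole numbers. The total that the authors used for RPM is not stated, but the count divided by its RPM gave 1 total per library, from 105372 reads (emerged replicate 2) to 9805286 (stem replicate 2). The listed miRNAs are a part of these totals. For the degradome, the authors deposited a simplified table of PAREsnip target sites for each library, with the transcript, category, position, p-value and alignment score, per the file headers. The deposited p-values are rounded and reach 0.05, and the deposited scores run from 2.0 to 4.0, where a lower score is better pairing. PAREsnip's version and settings are not given in the sources used here. Positions and coding-sequence limits are those of the authors' transcript models, and scaffold coordinates those of the authors' repeat names, on a build that is not given in the sources used here. Of 63 target genes, 0 matched the reference table of gene names, so targets keep the identifiers of the table.

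Libraries were grouped by the tissue and assay in the labels. The planned test for normalized values was limma; since the table holds counts, the planned test for counts was used in its place. Counts were tested with edgeR 4.0.16 (R 4.3.3) by quasi-likelihood, with the recovered totals as library sizes, TMM factors, the default expression filter, which kept 21 of 38 rows, and 1 fit over all 9 libraries with stage as the factor. The common biological coefficient of variation was 34.8%. Two-sided p-values were adjusted by Benjamini-Hochberg over the 21 miRNAs, with a threshold of 0.05, and the standard error was taken from the log2 change and its F statistic. The table is small and 3 families hold most of its reads, so the TMM factors, which ran from 0.495 to 1.80, set the scale of each comparison. Where a stage held 0 reads, its fold is a bound against 3 reads over the stage's pooled libraries, and where it held 1 to 3 reads, it is a ratio of pooled rates with an exact 95% interval. The intervals cover counting error only, and the floors only that of the stage at 0 reads. In a bound the mean RPM of the other stage is taken as exact. Bounds and ratios use RPM or the recovered totals, without TMM factors. Reads amplified by PCR are not independent molecules, so the true error can be larger.

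Per library, 3 reads were 0.312 RPM in the seedling and 0.398 and 0.306 RPM in stem. They were 3.76, 2.27 and 3.73 RPM in prehaustoria and 3.25, 28.5 and 4.43 RPM in emerged haustoria. Replicates of each stage differed by more than sampling noise (chi-square tests of counts, highest unadjusted p = 0.0315 over 7 couples of libraries). This approximation was used only to look for duplicated libraries and cannot show that samples are biologically separate. Each library was counted as 1 sample because the labels call the replicates biological.

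miRNA lists were fixed before the data were examined, as were the tests, the alternatives and the rule for named items, except where stated. The lists cover phase change, auxin signalling, meristem and organ transcription factors, the silencing machinery, nutrient and copper stress, NLR targeting, MYB or PPR targeting, *Cuscuta*-specific names and deeply conserved families. Lists with at least 3 tested members were tested with camera (limma 3.58.1) on log2(RPM + 1). The rule names each miRNA past the threshold, up to 20 per comparison, the list members with the strongest changes, the 10 with the highest mean level and, for the seedling, those beyond all other libraries by a margin of 1 (log2). For the degradome it names the best site per family, by category and then p, for up to 25 families. Tag abundance was not used here, so ties were broken by score and by the number of libraries. Other sites and miRNAs named were chosen after their values were seen, among them the further miR167 sites, the miRNAs at 0 reads in the seedling and the rare miRNAs of the closing section.

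Stage profiles were compared by a permutational multivariate analysis of variance over all assignments of 8 libraries, and summed levels by exact permutation tests (Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3). Shares of category 0 sites were compared with Fisher's exact test and given Clopper-Pearson intervals. A site is 1 family, transcript and position. The overlap between and within stages was compared over the 3 splits of the 4 degradome libraries, a test added after the data were seen. Plots were drawn with matplotlib 3.10.9.

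The fit was tested on 100 simulated datasets of the 21 miRNAs. For emerged haustoria against prehaustoria it called 21.0%, 62.5% and 89.0% of miRNAs changed 2-, 4- and 8-fold and 1.20% of unchanged ones. Against stem the shares were 16.0%, 57.0% and 77.5% (unchanged 2.10%) for prehaustoria and 13.5%, 42.0% and 68.0% (unchanged 2.30%) for emerged haustoria. Most simulated miRNAs were unchanged, while in each real comparison with stem 19 of 21 passed. These shares therefore do not measure the error against stem when most miRNAs change. Within a comparison all simulated libraries had the same rates, apart from the changed miRNAs, and the same dispersion. No difference in scale factor was simulated, so in no comparison do the shares cover error from the TMM factors. Camera called 2% of unchanged lists of 4 miRNAs.

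Alternatives were DESeq2 1.42.0, median-ratio factors, no expression filter, a mean RPM of at least 10, limma with pseudocounts of 0.1, 1 and 10 and without trend, only the stages compared, the replicate number as a block, and each replicate left out. For the lists they were fry, an estimated correlation, the block and the other pseudocounts. For sites they were other categories, a p of at most 0.01, and other definitions of a shared site. Added after the data were seen were limma on log2(RPM + 1), the authors' totals without TMM, stem and seedling thinned to 798194 reads, TMM factors held in the fits without a replicate and with the block, the haustorial stages alone, sites by position under any family name, isoforms counted as 1 gene, each degradome library left out, bounds and count ratios with each library left out, and bounds from pooled rates. The seedling has 1 library and went into no test between stages other than 1 alternative against stem. Overlap of the calls of the comparisons that share stem libraries was not analysed here.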

Results

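Small RNAs were sequenced from *Cuscuta campestris* (field dodder), a parasitic plant that winds around a host stem and enters it through an infection organ, the haustorium. The 9 small-RNA libraries came from seedlings (n = 1), non-infective vine tips, called stem here (n = 2), shoot segments at the prehaustorial stage (n = 3) and segments with emerged haustoria (n = 3). Haustoria were induced by far-red light and touch, per the labels' protocols. A further 4 libraries were degradome (PARE) libraries, which sequence the 5′ ends of cleaved RNAs and so mark the sites where miRNAs cut their targets. They came from prehaustoria (n = 2) and emerged haustoria (n = 2). Library totals, recovered from the deposited counts and RPM (reads scaled to an equal library total), were 9601870 reads for the seedling, and 7538327 and 9805286 reads for stem replicates 1 and 2. They were 798194, 1319651 and 803401 reads for prehaustoria replicates 1 to 3 and 922064, 105372 and 676956 reads for emerged replicates 1 to 3. The smallest of the stem and seedling libraries was thus 5.71 times deeper than the largest haustorial one. A floor of 3 reads corresponded to 0.306 to 0.398 RPM in stem and 2.27 to 28.5 RPM in the 6 haustorial libraries, the highest being emerged replicate 2. Levels are given as mean RPM ± SD. The labels call the replicates biological without naming separate plants or cultures, so p-values measure only the spread between these libraries.

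The miRNA pool was dominated by miR156, miR159 and miR166, which together held 97.6% of the miRNA reads in stem (97.4 to 97.7) and 80.1% in the seedling. They held 81.8% in prehaustoria (79.1 to 86.0) and 77.1% in emerged haustoria (75.2 to 78.5). miR156, which represses SPL transcription factors and maintains the juvenile phase, held 45.2% of the stem miRNA reads and miR159, a repressor of GAMYB-type MYB factors, 40.9%. In prehaustoria and emerged haustoria the leading miRNA was miR166, which cuts HD-ZIP III mRNAs, with 43.0% and 53.1%. The other families among the 10 with the highest mean level were miR319, miR396, miR398, miR408, miR172, miR168 and miR160. Members of the near-identical families miR156 and miR157, miR159 and miR319, miR165 and miR166, and miR170 and miR171 can share reads, so the division of reads within each of these couples is uncertain.

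**Figure D1:**
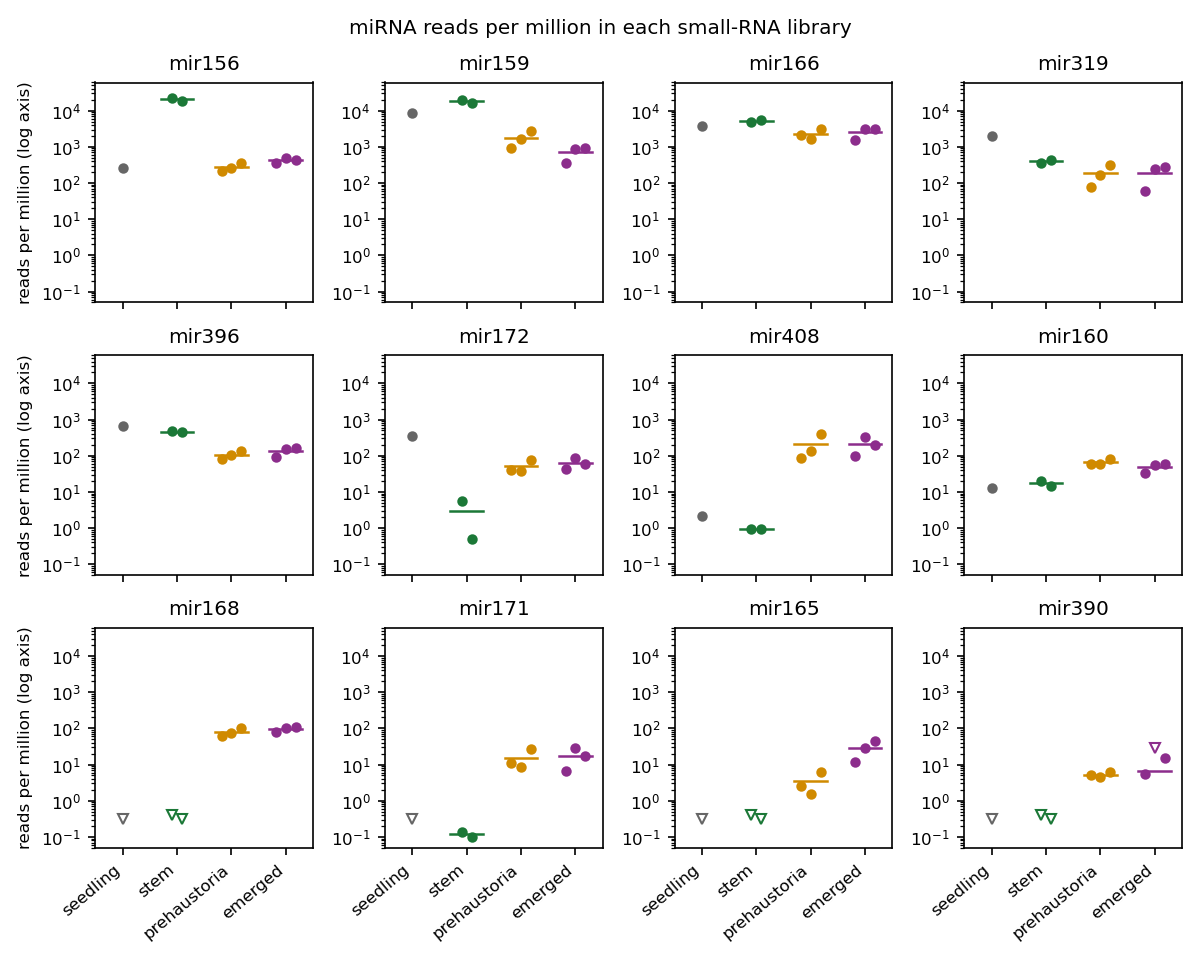
RPM (log axis) of 12 miRNAs in each small-RNA library, by stage; dots are libraries, lines are stage means, and open triangles mark libraries with 0 reads at the value of 3 reads. miR156 stood at 20481 RPM in stem and 274 RPM in prehaustoria, and miR168 had 0 reads in stem.

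Prehaustoria were compared with stem to ask which miRNAs differ between induced segments and non-infective vine tips. Haustorium formation, the far-red light and touch treatment, the part of the shoot and library depth go together here and cannot be told apart. miR156 fell from 20481 ± 2182 RPM in stem (SD, n = 2) to 274 ± 64.9 RPM in prehaustoria (SD, n = 3), and miR159 fell from 18498 ± 2501 to 1751 ± 933 RPM. miR172, which represses AP2-like factors and promotes the adult phase, rose from 3.04 ± 3.58 to 51.7 ± 21.0 RPM. miR408, a copper-responsive miRNA that targets blue copper proteins, rose from 0.923 ± 0.008 to 208 ± 169 RPM. miR168, which targets the mRNA of the silencing protein AGO1, had 0 reads in both stem libraries and stood at 79.4 ± 20.4 RPM in prehaustoria, at least 459-fold higher.

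In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 21 tested miRNAs, 19 passed an adjusted p of 0.05, of which 14 rose and 5 fell. Fitted changes are on the TMM scale, which placed the median log2 change of these miRNAs 1.12 higher than the authors' totals did. Bounds and count ratios use RPM or the authors' totals without TMM factors. On the TMM scale rises against stem are larger and falls smaller. miR157, for example, was 51.0-fold lower by pooled rates and 23.2-fold lower in the fit. In edgeR the log2 change of miR156 was −5.12 (SE 0.322, adjusted p = 5.71e-15), a 34.8-fold decrease, and that of miR159 −2.40 (SE 0.268, adjusted p = 2.5e-09). The edgeR log2 change of miR408 was 8.69 (SE 0.684, adjusted p = 1.08e-12) and that of miR172 5.11 (SE 0.735, adjusted p = 2.74e-07). miR172 rested on 42 and 5 reads in the stem libraries, and its log2 change was 7.67 without stem replicate 1 and 4.18 without stem replicate 2. miR408 moved to 7.66 and miR159 to −3.09 without prehaustoria replicate 3. miR160, which targets auxin response factors, rose by 3.04 (SE 0.555), and miR3630 by 4.87 (SE 0.834; 3.92 without prehaustoria replicate 2). miR396, which represses growth-regulating factors, fell by 1.03 (SE 0.384, adjusted p = 0.0136). Against the floor of 3 reads over the pooled stem libraries (0.173 RPM), miR8175 was at least 45.6-fold, miR170 at least 30.8-fold, miR390 at least 30.4-fold and miR165 at least 19.7-fold higher in prehaustoria. The bound of miR8175 was 2.53 times lower without prehaustoria replicate 2, and those of miR170 and miR165 were 17.4 and 11.6 without prehaustoria replicate 3. From pooled rates the bounds of miR8175, miR170, miR390 and miR165 were 55.4, 27.7, 29.7 and 17.8. Neither form covers the counting error of the prehaustorial reads. Without stem replicate 1 or 2 the floor is 0.306 or 0.398 RPM, which lowers each bound of a rise against stem, that of miR168 included, by more than 1.5 times. miR171, a repressor of GRAS factors, had 2 stem reads and a count ratio of 125 (95% interval 32.4 to 1060; 81.9 without prehaustoria replicate 3). miR845, known for targeting retrotransposons in *Arabidopsis*, had 1 stem read and a ratio of 160 (26.4 to 6560; 90.6 without stem replicate 1, and with 0 stem reads left a bound of 22.9 without stem replicate 2). miR157 stood at 606 stem reads against 2 in prehaustoria, 51.0-fold lower (14.1 to 422; 28.0 without prehaustoria replicate 2, and at least 25.7 without prehaustoria replicate 1). miR397, which targets laccases, had 197 stem reads and 0 in prehaustoria, at least 11.5-fold lower (6.33 without prehaustoria replicate 2). Of all 21 tested, 19 had the 3 prehaustorial libraries beyond both stem libraries, 12 higher and 7 lower, where chance gives 20%, or 4.2 miRNAs; the ranges of miR164 and miR398 overlapped.

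With the authors' totals alone, 11 miRNAs rose and 6 fell in the same edgeR test: miR164, which targets NAC factors (log2 change 1.92, SE 0.565), miR167, which targets auxin response factors (2.53, SE 0.687; 3.32 without stem replicate 1), and miR398, which targets copper superoxide dismutases (1.28, SE 0.525), no longer passed, while miR166 did, with a log2 change of −1.18 (adjusted p = 0.0208, range over its alternatives 0.0208 to 0.987) against −0.06 on the TMM scale. The log2 change of miR398 turned to −0.11 without prehaustoria replicate 3 and to −0.23 in limma on log2(RPM + 1); its adjusted p ranged from 0.000347 to 0.991 over its alternatives. miR396 missed the threshold without stem replicate 1 (log2 change −0.87) and miR164 without prehaustoria replicate 3 (1.41). In limma on log2(RPM + 1) 4 of the 19 calls were lost, those of miR164, miR167, miR398 and miR3630.

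**Figure D2:**
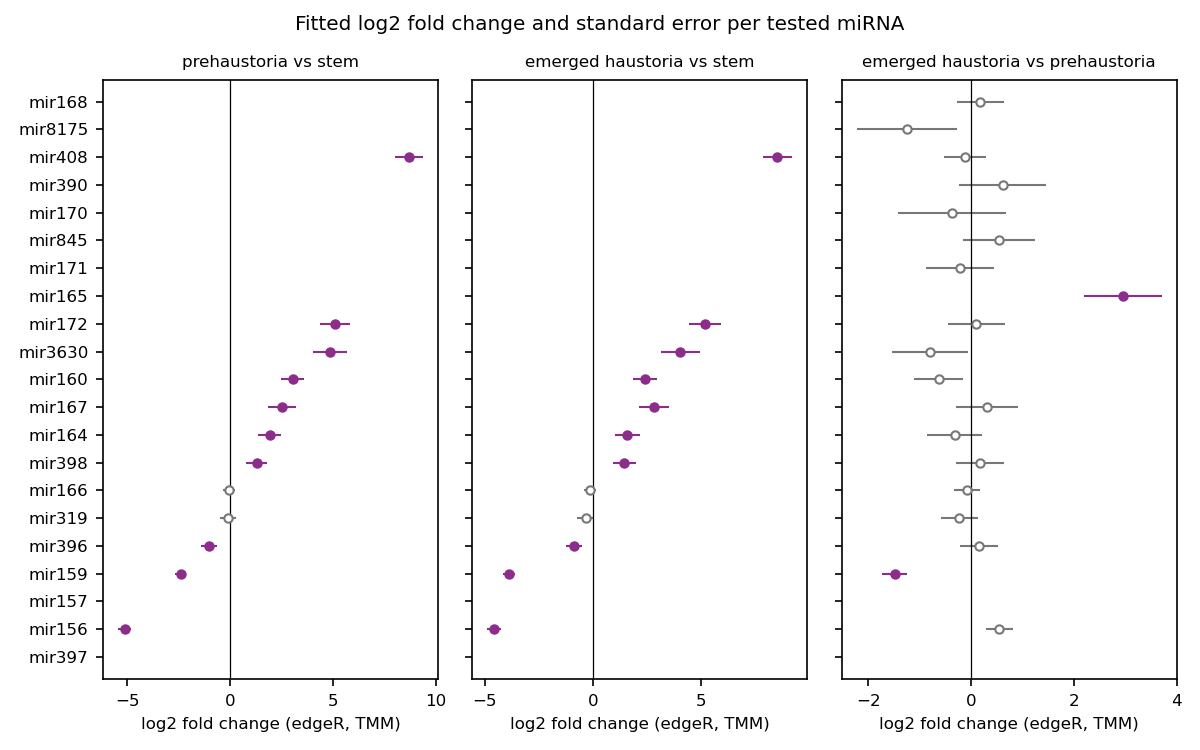
Fitted log2 fold change (x axis, edgeR with TMM) and standard error (bars) of each miRNA in the 3 comparisons; filled symbols passed an adjusted p of 0.05. miRNAs with 3 or fewer reads in a group are left out, which leaves 12, 12 and 19 of the 21 tested; miR408 lay at 8.69 and miR156 at −5.12 in prehaustoria against stem.

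Emerged haustoria were compared with the same stem libraries. miR156 fell to 437 ± 71.4 RPM (SD, n = 3) and miR159 to 713 ± 309 RPM, while miR408 rose to 212 ± 116 RPM and miR172 to 62.1 ± 21.4 RPM. miR168 reached 96.6 ± 15.2 RPM, at least 559-fold above the stem floor, and miR165, a near-identical relative of miR166, reached 28.7 ± 16.9 RPM, at least 166-fold above it. Without 1 stem library these bounds are lower by more than 1.5 times, as above. Of 21 tested miRNAs 19 passed, with 14 rising and 5 falling.

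In edgeR the log2 change was −4.57 for miR156 (SE 0.316, adjusted p = 7.44e-14), −3.88 for miR159 (SE 0.281, adjusted p = 1.22e-13), 8.56 for miR408 (SE 0.683, adjusted p = 8.72e-13) and 5.21 for miR172 (SE 0.747, adjusted p = 2.27e-07; 7.77 without stem replicate 1 and 4.28 without stem replicate 2). miR3630 rose by 4.06 (SE 0.889), miR167 by 2.83 (SE 0.704; 3.64 without stem replicate 1 and 2.10 without emerged replicate 1), miR160 by 2.41 (SE 0.555), miR164 by 1.60 (SE 0.588) and miR398 by 1.45 (SE 0.538), and miR396 fell by 0.87 (SE 0.391, adjusted p = 0.0361). miR170 was at least 47.2-fold higher by mean RPM, which 2 reads in emerged replicate 2 raised, and at least 20.4-fold by pooled rates. miR390, which starts the production of TAS3 small RNAs, was at least 38.9-fold higher and miR8175 at least 19.2-fold. These bounds rested on single libraries: without emerged replicate 2 that of miR170 was 15.9 and that of miR390 58.4, and without emerged replicate 3 those of miR390 and miR8175 were 15.7 and 3.13. They too are lower by more than 1.5 times without 1 stem library. miR845 had a count ratio of 244 (95% interval 39.8 to 10000; 138 without stem replicate 1, and a bound of 32.8 without stem replicate 2) and miR171 one of 107 (26.1 to 940; 166 without emerged replicate 1). miR157 was 19.9-fold lower on 3 reads (6.76 to 96.5; 35.9 without emerged replicate 3). miR397 was at least 6.74-fold lower on 0 reads (3.09 without emerged replicate 1, 4.06 without emerged replicate 3). Of all 21 tested, 15 had all emerged libraries beyond both stem libraries, 8 higher and 7 lower, where chance gives 20%, or 4.2 miRNAs. The exceptions were miR164, miR167, miR3630, miR390, miR398 and miR8175. Among the 7 lower, miR157 and miR397 had 0 reads in emerged replicate 2, where 3 reads are 28.5 RPM. In stem replicate 2 they stood at 26.1 and 8.06 RPM, so emerged replicate 2 could not place them below both stem libraries.

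On this comparison the TMM scale lay 1.17 above the authors' totals in the median log2 change. With the authors' totals alone 10 miRNAs rose and 5 fell, and miR160 (adjusted p = 0.0556), miR167 (0.0532), miR164 and miR398 (both 0.349) did not pass; their adjusted p over all alternatives reached at most 0.0556, 0.939, 0.37 and 0.73, and started at 8.25e-06, 3.31e-07, 0.00213 and 0.000124. In limma on log2(RPM + 1) 6 of the 19 calls were lost, those of miR164, miR167, miR3630, miR390, miR398 and miR8175. Emerged replicate 2 held 0 reads of miR167, miR3630, miR390 and miR8175, and the log2 change of miR167 turned to −0.88 in limma on log2(RPM + 0.1). Single libraries also ended calls: miR396 without stem replicate 1 (−0.71), emerged replicate 2 (−0.66) or emerged replicate 3 (−0.70), miR164 without stem replicate 2 (1.36), miR398 without stem replicate 1 (1.46) or 2 (1.43), and miR397, by its adjusted p alone, without emerged replicate 3.

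The step from prehaustoria to emerged haustoria was the comparison of 3 against 3 libraries. miR165 rose from 3.42 ± 2.48 to 28.7 ± 16.9 RPM (SD, n = 3 each), which rested on 9 and 45 reads. miR159 fell from 1751 ± 933 to 713 ± 309 RPM. miR165 targets HD-ZIP III factors and miR159 MYB factors. miR166 cuts HD-ZIP III mRNAs as well, and miR165 made up 0.142% of the reads of both in prehaustoria. In emerged haustoria it made up 1.16%, so its rise does not show a change in their summed level. miR166 (2286 ± 731 and 2576 ± 928 RPM), miR408 (208 ± 169 and 212 ± 116 RPM) and miR168 (79.4 ± 20.4 and 96.6 ± 15.2 RPM) did not pass.

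In edgeR's test 2 of 21 miRNAs passed. The edgeR log2 change was 2.95 for miR165 (SE 0.757, adjusted p = 0.00546), higher in 3 of 3 emerged libraries than in every prehaustorial library, and −1.49 for miR159 (SE 0.247, adjusted p = 2.66e-05), lower than the prehaustorial mean in 3 of 3 and below every prehaustorial RPM in 2 of 3. miR156 also had an unadjusted edgeR p of 0.0498 (log2 change 0.55, SE 0.269, adjusted p = 0.349). The groups did not overlap for 3 of the 21 miRNAs, miR156 and miR165 higher and miR160 lower, where chance gives 10%, or 2.1 miRNAs.

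Limma on log2(RPM + 1) called 0 miRNAs in this comparison (2 at an unadjusted p of 0.05), and DESeq2 called 2. With the authors' totals, 1 rose and 0 fell: miR159 had an adjusted p of 0.0628 (range over its alternatives 1.5e-10 to 0.569) at a log2 change of −1.30, while the TMM scale lowered the median change by 0.17 (log2). miR159 lost its call without emerged replicate 2 (−0.52, adjusted p = 0.335), emerged replicate 3 (−0.61, 0.274) or prehaustoria replicate 3 (−0.62, 0.274) when the TMM factors were estimated anew, which raised the median log2 change to 0.73, 1.03 and 0.78, and kept it with the factors held. miR165 lost its call without emerged replicate 3 with the factors held (2.59, adjusted p = 0.144; range 0.000127 to 0.144). With the factors estimated anew its log2 change was 4.20 without prehaustoria replicate 3, 4.10 without emerged replicate 2 and 3.60 without emerged replicate 3.

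By function, all 4 tested miRNAs of the auxin list rose against stem in both haustorial stages: miR160 and miR167, which target auxin response factors, miR390, which acts on them through TAS3 small RNAs, and miR164, which targets NAC factors downstream of auxin. In limma on log2(RPM + 1), miR164 and miR167 passed in neither comparison and miR390 not in emerged haustoria. In the phase-change list miR172 rose and miR156 and miR157 fell in both comparisons with stem. In the single seedling library miR156 (257 RPM) and miR157 (1.04 RPM) also lay below stem, and miR172 (355 RPM) above it. The pattern was thus not particular to the haustorial stages. Of the 8 tested miRNAs of the meristem and organ list, 4 rose (miR164, miR165, miR170 and miR171), 2 fell (miR159 and miR396) and 2 did not pass (miR166 and miR319). In the nutrient and copper list miR408 and miR398 rose and miR397 fell. The call of miR398 held in 3 of 23 alternatives in prehaustoria, with the opposite sign in 6, and in 9 of 23 in emerged haustoria. Of the silencing list miR168 and miR390 rose. Among the 16 tested deeply conserved families, 10 rose and 4 fell. Between the haustorial stages miR165 rose and miR159 fell, both in the meristem list and in the conserved list, and no member of the auxin, phase-change, copper or silencing lists passed. Adjusted over the list alone, the counts of risen and fallen members were identical in all of these lists. With the authors' totals, miR164, miR167 and miR398 passed in neither comparison with stem and miR160 not in emerged haustoria. The libraries compared with stem also differed from it in depth, by at least 5.71 times. With stem and seedling thinned to 798194 reads, edgeR called 19 miRNAs in prehaustoria and 18 in emerged haustoria, where miR396 did not pass.

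No list differed from the other miRNAs in camera with a preset correlation of 0.01. Of 15 tests over 5 lists and 3 comparisons, 0 passed (adjusted p of 0.802 in each, 0.843 with an estimated correlation), and 0 had an unadjusted p under 0.05. Limma's fry, which asks whether a list's members move one way on balance, called 2, the phase-change list in prehaustoria (adjusted p = 0.00247) and in emerged haustoria against stem (adjusted p = 0.00287), both downward although miR172 rose; its adjusted p for the auxin list was 0.0591 and 0.149. Lists with fewer than 3 tested members were not tested, which covered the silencing list with 2 and the *Cuscuta* list, whose 1 member with a level, miR11592, had 1 stem read. No member of the lists of NLR-targeting and of MYB- or PPR-targeting miRNAs has a level in the table; miR482 and miR858 had degradome sites.

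The seedling library stood apart in 2 miRNAs. miR319, which represses TCP factors, was at 2041 RPM in the seedling against at most 431 RPM in the 8 other libraries, a margin of 2.24 (log2). miR172 was at 355 RPM against at most 85.4 RPM, a margin of 2.04. No miRNA lay below all others by a margin of 1. In the seedling miR156 was at 257 RPM and miR159 at 8695 RPM, while miR168, miR165, miR170 and miR390 had 0 reads, which allows up to 0.312 RPM each. With 1 library these differences have no replicate check.

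Whole profiles were compared over the stages. A permutational multivariate analysis of variance on log2(RPM + 1) over stem, prehaustoria and emerged haustoria gave a pseudo-F of 8.91 (exact permutation p = 0.0214 over 560 assignments, smallest possible 0.00357), with 78.1% of the variation between stages. Prehaustoria and emerged haustoria alone gave a pseudo-F of 0.971 (exact permutation p = 0.6, smallest possible 0.1). Without stem replicate 1 or 2, or prehaustoria replicate 2 or 3, p was above 0.05 (pseudo-F 4.47, 4.43, 7.47 and 8.06; exact permutation p = 0.0857, 0.0857, 0.0857 and 0.0571).

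The listed miRNAs together made up 4.53% ± 0.416 of stem reads (SD, n = 2), 0.531% ± 0.217 of prehaustorial reads (SD, n = 3) and 0.485% ± 0.175 of emerged reads (SD, n = 3), and 1.57% of seedling reads. The summed level differed from stem by −3.16 (log2) in prehaustoria and −3.30 in emerged haustoria, 8.94-fold and 9.83-fold lower. Each two-sided exact permutation p was 0.1, the smallest that these group sizes allow. The haustorial stages differed by −0.14 (exact permutation p = 0.9, smallest possible 0.1), which turned to 0.20 without miR159, to 0.21 without emerged replicate 1 and to 0.18 without prehaustoria replicate 3.

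The degradome libraries show where miRNAs cut transcripts in each haustorial stage. The authors' PAREsnip calls place each site in a category from 0, where the cleavage tag is the highest on its transcript, to 4, where it rests on 1 read. Strong sites of miR393, which targets auxin receptors, miR167, miR166 and miR164 recurred across the libraries. The miR393 variant TCCAAAGGGATCGCATTGAT had a category 0 site in all 4 libraries at position 1600 of transcript Cc018236.t1, inside its coding sequence (85 to 1812), with an alignment score of 2.0. For miR167 the sites at 2811 of Cc027677.t1 (coding sequence 479 to 3091) and 2778 of Cc034367.t1 (563 to 3019) were category 0 in all 4, and those at 2743 of Cc031191.t1 and 2767 of Cc047578.t1 in 3 of 4. The miR166 variant CCGGACCAGGCTTCATCCCC cut at 1498 of Cc002635.t1 (928 to 3453), with category 0 in prehaustoria replicate 2 and 1 in both emerged libraries. The same position was listed in prehaustoria replicate 1 under miR5168, as category 0. The miR164 site at 2768 of Cc017493.t1 (243 to 2822) was category 0 in prehaustoria replicate 1 and emerged replicate 2 and category 2 in the other libraries.

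Sites of lower category included those of 3 miRNAs that rose against stem, miR845, miR168 and miR390. miR845 had a site in all 4 libraries, at 1081 of Cc011098.t1 (coding sequence 258 to 1121), with category 2 in 3 libraries and 4 in emerged replicate 1. miR168 had its best site at 721 of Cc021107.t1 (85 to 3534) and miR390 at 746 of Cc012687.t1 (229 to 1344), each category 4 in 1 library. The other families named here have no miRNA level in the table. miR827, linked to phosphate supply, had a site in all 4 at 718 of Cc033748.t1 (146 to 1156), with category 2 in emerged replicate 1 and 3 elsewhere. miR868 was listed at 2302 of Cc022267.t1 and miR780 at 3140 of Cc041483.t2, in the 3′ UTR, each with a best category of 2. The best sites of miR162 (1384 of Cc044334.t1, 3′ UTR), miR163 (296 of Cc034911.t1) and miR858 (400 of Cc009469.t1, 5′ UTR) were category 4 in 1 library each.

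Sites in annotated repeats made up 86 of the 168 distinct sites, 51.2%, and 43 of the 59 distinct miR156 sites. The family name miR156 joins listed variants of different sequence, and which of them repress SPL factors was not examined. These counts therefore do not show that the SPL-repressing miR156 cuts mainly repeats. Whether a tag in a repeat also matches other copies of that repeat was not examined either. The best miR156 site was category 0 in prehaustoria replicate 1, at position 61 of a repeat on scaffold 363 (161172 to 161591, plus strand), and that of miR5025 category 0 in prehaustoria replicate 2, at position 98 of a repeat on scaffold 586 (40739 to 40889). The families listed as Ccamp-miR17 and Ccamp-miR13 had category 0 sites in repeats on scaffold 175 (44178 to 44258) and scaffold 83 (190923 to 191026), and Ccamp-miR16 a category 2 site on scaffold 2330 (774 to 1668). Repeats also held the best sites of miR773 (scaffold 316) and miR5029 (scaffold 90), both category 2, and of miR403 (scaffold 258), miR847 and miR846 (both scaffold 84) and miR477 (scaffold 1499), all category 4. Of the repeat sites, 40 lay in RLX, 27 in RLG and 13 in RLC elements, codes for LTR retrotransposons, and 6 in repeats coded XXX. The remaining sites fell in coding sequence (50), 5′ UTRs (17) and 3′ UTRs (15).

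The number of distinct sites per library was 71 and 77 in prehaustoria and 84 and 92 in emerged haustoria. Category 0 sites made up 18.3% (95% exact Clopper-Pearson interval 10.1 to 29.3) and 15.6% (8.32 to 25.6) in the prehaustorial libraries, and 9.52% (4.20 to 17.9) and 10.9% (5.34 to 19.1) in the emerged ones. Over both libraries of a stage, 20 of 112 sites (17.9%) in prehaustoria and 14 of 118 (11.9%) in emerged haustoria were category 0, an odds ratio of 0.619 (two-sided Fisher's exact p = 0.265). Among categories 0 and 1 only, the odds ratio turned to 1.05 (Fisher's exact p = 1). Sites are not replicates, so this test compares these libraries, and their read depth is not known here. A site in both libraries of a stage entered with its best category. The stages share 62 sites, and isoforms of a gene count separately, so the sites are not independent as the test assumes. For isoforms this holds for the intervals too. With sites counted once per family and gene, the odds ratio was 0.675 (Fisher's exact p = 0.423). Positions listed under both miR166 and miR5168 count as separate sites in these numbers.

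**Figure D3:**
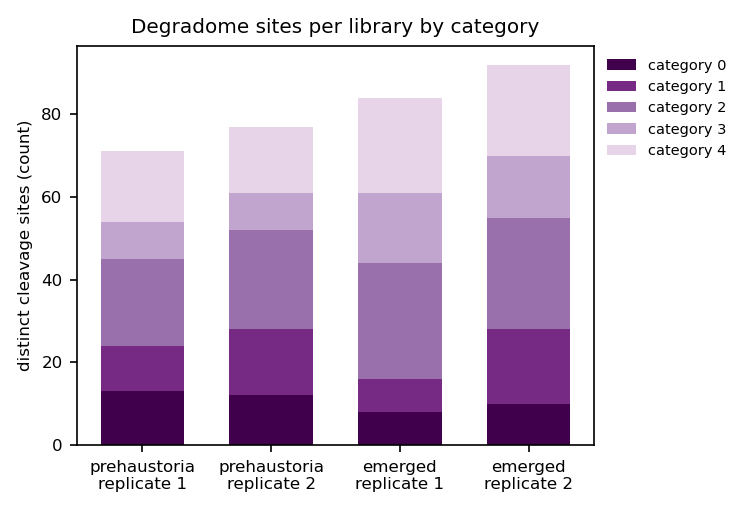
Distinct miRNA cleavage sites (count) in each degradome library, stacked by PAREsnip category from 0 (dark, strongest) to 4 (light). Totals were 71, 77, 84 and 92, with 13, 12, 8 and 10 category 0 sites.

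Sites were then compared between stages by miRNA family, transcript and position. Of the 168 sites, 29 were in all 4 libraries, among them those of miR393, miR167, miR164 and miR845 named above, 62 in both stages and 92 in 1 library. Entries of miR166 and miR5168 at the same position count as separate sites here. The share of sites in common (Jaccard index) averaged 35.9% between a prehaustorial and an emerged library (32.5 to 38.5), and was 32.1% between the prehaustorial and 49.2% between the emerged replicates. The mean between stages differed by −4.79 percentage points from that between replicates, less than the gap between the replicate values. In an exact permutation test over the 3 splits of the 4 libraries into couples this gave p = 0.333, the smallest that 3 splits allow. Sites were also compared by transcript and position under any family name, which joins the miR5168 and miR166 entries. The share was then 39.4% between stages (37.6 to 42.2), 39.6% between the prehaustorial and 49.2% between the emerged replicates, a difference of −4.98 points.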

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

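The authors' totals alone, thinning, TMM factors held, limma on log2(RPM + 1) and the haustorial stages alone were chosen after the data were seen. So were isoforms counted as 1, sites by position under any family name and single degradome libraries left out. Bounds with single libraries left out and bounds from pooled rates were also chosen then. The other alternatives were planned. Over the main results, 4 alternatives turned a direction, 5 ended a call and 12 moved a count by more than 1.5 times. For each named miRNA, the fits without 1 library entered only as the weakest, with TMM factors estimated anew and held. On that count 7 alternatives turned a direction, none of which passed, and 89 others ended a call. Calls therefore ended in more single fits than these. For emerged haustoria against prehaustoria (2 miRNAs), limma on log2(RPM + 0.1), log2(RPM + 1) and log2(RPM + 10) called 0, 0 and 0, limma without trend 1 and the authors' totals 1, and leaving out 1 library gave 1 to 3. For prehaustoria against stem (19), limma on log2(RPM + 10) called 12 and a mean RPM of at least 10, with 14 miRNAs tested, 11; for emerged haustoria against stem (19) both gave 12. Limma called 8 miRNAs between seedling and stem, with the lone seedling assumed to vary like the other stages. The pseudo-F ran from 4.43 to 14.1 without 1 library and was 0.971 for the haustorial stages alone. The summed level of emerged haustoria against prehaustoria (−0.14) ran from −0.34 to 0.21 without 1 library and was 0.20 without miR159. The odds ratio of category 0 sites (0.619) was 1.05 among categories 0 and 1, and fry called 2 lists against 0.

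The log2 change of miR398 in prehaustoria against stem (1.28) was −0.24, −0.23 and −0.15 in limma with pseudocounts of 0.1, 1 and 10, −0.23 without trend, −0.11 at its lowest without 1 library (0.66 with TMM factors held), and −0.0054 with the replicate block. That of miR167 in emerged haustoria against stem (2.83) was −0.88 in limma with a pseudocount of 0.1. The cause of these changes was not tested, apart from the fewer miRNAs tested under the RPM minimum. Same-numbered libraries had correlations from −0.52 to 0.38 over 7 couples, 5 of them above 0.1. These were taken after removing stage means of few libraries, so they cannot tell whether the numbers pair the samples. With the replicate block the counts were 3, 18 and 16 for emerged against prehaustoria, prehaustoria against stem and emerged against stem, and 2, 18 and 17 with TMM factors held. In emerged against prehaustoria the block called miR165, miR156 and miR398 and not miR159 (−0.52, adjusted p = 0.25, range over its alternatives 1.5e-10 to 0.569), and with the factors held miR165 and miR159. In emerged against stem the block ended the edgeR calls of miR157 (adjusted p = 0.0617), miR396 (0.286) and miR397 (0.161). In prehaustoria against stem it ended those of miR164 (adjusted p = 0.0587) and miR398 (0.991). Over all alternatives, miR156, miR159, miR168, miR171, miR172 and miR408 passed against stem in both comparisons, and miR845 in all but the RPM minimum, which left it untested. A correlation of cleavage tags with miRNA changes was planned and not run, since tag abundance was not used here. Depth limits emerged replicate 2 most, where 1 read is 9.49 RPM.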

Other observations

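All tests in this part were chosen after the result was seen. The edgeR fits quoted for miR159, over all libraries and without emerged replicate 2, were planned.

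Among miRNAs too rare to be tested, miR169, which targets NF-YA factors, had 77 reads in stem and 5 in the seedling and 0 in the 6 haustorial libraries, where the stem rate would give 20.5 reads; it was at least 4.33-fold lower in prehaustoria and at least 2.53-fold lower in emerged haustoria than in stem. These bounds were 2.37 without prehaustoria replicate 2, and 1.16 and 1.52 without emerged replicates 1 and 3. They use RPM without TMM factors, and on the TMM scale a fall against stem is smaller. miR6173 had 19 stem reads and 0 haustorial reads, where 5.07 would be given by the stem rate. In the other direction, miR5083 had 5 reads in 3 haustorial libraries and 0 in stem and seedling, and miR829 had 3 reads in 3 haustorial libraries. miR5658 had 9 haustorial, 4 stem and 1 seedling reads. In the degradome, 22 of the 31 families with sites, holding 77 of the 168 sites, have no miRNA level here; 5 of these families, miR393, miR827, miR847, Ccamp-miR13 and Ccamp-miR16, had sites in all 4 libraries.

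miR165, miR168, miR170 and miR390 had 0 reads in stem and seedling and 20 to 385 reads in the haustorial libraries. Lower depth was no possible account of these zeros, since stem and seedling are the deeper libraries, by at least 5.71 times. At the pooled haustorial rate stem and seedling would hold at least 117 reads of each. That number follows from the library depths and from the choice of these miRNAs, so it tests nothing. Reads of miR170 counted as miR171 are argued against, since the summed level was 199 times higher in the haustorial libraries than in stem. Both remaining accounts stay open. Reads of miR165 could have been counted as miR166 in stem, and miR165 makes up too little of the summed haustorial reads of both, 0.528%, to tell. The library set could matter, since stem and seedling are the deep libraries and no label names a batch. That 4 of the 4 miRNAs were at 0 in the seedling as well as in stem decides nothing, since they were chosen for it. miR8175, with 0 stem reads, had 2 seedling reads. A biological difference between haustorial segments and other tissue is a hypothesis that remains untested, since tissue, light and touch treatment and library set go together.

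miR165 rose and miR159 fell in emerged haustoria against prehaustoria. Reads moved between miR159 and miR319 are argued against, since the highest miR319 level of an emerged library, 269 RPM, is below the 1037 RPM that miR159 lost on average. A constant misreading of miR166 as miR165 would keep the share of miR165 among their reads alike in both stages. The share was 0.0931% to 0.202% in the prehaustorial libraries and 0.786% to 1.44% in the emerged ones. These rest on 2 to 5 and 3 to 31 reads of miR165. This argues against a constant misreading only as far as the call of miR165 holds. miR165 was chosen for its rise, so the share is not independent of that call. A shift of all miRNAs alike is argued against as the whole cause of the miR159 fall, since miR159 lay below the median change of the tested miRNAs by −1.25 (log2) or further in the edgeR alternatives. The limma alternatives were left out of this comparison. It uses the libraries and fits that gave the call, so it is not independent of that call. How far miR159 fell stays open to the scale factors. Its log2 change was −1.49 (SE 0.247) and rose to −0.52 (SE 0.411) at its highest, without emerged replicate 2, where factors estimated anew raised the median change and ended the call. Of the 10 splits of the 6 libraries, 1 gave as many calls, the real split with 2, and the highest of the other splits gave 0; 10 splits are too few for a share under 0.05. A difference between the stages may remain as a biological hypothesis, with 45 emerged reads of miR165 behind it.

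In prehaustoria replicate 1 no site was listed under miR166 and 6 under miR5168, a name listed in no other degradome library. A candidate explanation is 1 site under different names: 6 of the 6 miR5168 positions were listed under miR166 in other libraries, and the variants differ by C1T, T16A and C17T over the shared length, counted from the 5′ end of the miR166 variant CCGGACCAGGCTTCATCCCC to the miR5168 variant TCGGACCAGGCTTCAATCC. Loss of miR166 cleavage is argued against, since 1 of the 7 miR166 positions found in each of the other 3 libraries was missing there under any name, 1068 of Cc008901.t1. No biological explanation was tested, since the design puts both prehaustorial libraries in 1 group.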
